A study of Danio rerio with 3 samples.

How the data were processed

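RNA was taken from pools of whole zebrafish embryos kept at 28 ± 0.5 °C and collected at 24 hours post-fertilization, 400 embryos per group. Per the labels' protocols and the series' design text, total RNA was extracted with Trizol, biotin-labelled cRNA was hybridised to a 1-colour Affymetrix array, fertilization fell within 5 minutes and injection within 30 minutes, and embryos of all parents were mixed before they were divided. The 3 groups, uninjected, control siRNA and PGRP-SC siRNA, each had 1 array. The own label of the PGRP-SC sample names the target without the word siRNA, which was taken from the design text.

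The deposited table held 1 linear signal intensity per probe set and array. Per the submitters' processing notes the software was GCOS 1.4, and further settings were not given in the sources used here. The values carried a global scaling: the mean over all probe sets after removing 2% from each tail was 500.1 in each of the 3 arrays. The table held no detection calls. Such scaling sets the overall level of the arrays equal, so a difference in total RNA per embryo cannot be seen in these values. Of the 15617 probe sets, 115 were the array maker's controls and were kept out of counts and lists, which left 15502. The platform annotation named 1 gene for 10795 of them, several for 135 and none for 4572, and a gene was taken only from a probe set with 1 gene. Current symbols came from the reference gene table for the 10711 probe sets whose gene ID it held, which changed 1 symbol.

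Signals were scaled again to a common 2% trimmed mean over the analysed probe sets, with factors of 1.00, 0.999 and 1.00 for uninjected, control siRNA and PGRP-SC siRNA. Signals under the 40th percentile pooled over the arrays, 101.7, were set to it. This floor held 39.7%, 39.9% and 40.4% of the probe sets in the 3 arrays, and 5332 probe sets were under it in all of them. Log2 ratios were then taken between arrays. A ratio with 1 side under the floor is a bound, and where both sides were under it no ratio was given. Probe sets were counted at a ratio of at least 2, higher and lower apart, in each comparison and against both other arrays. Differences of a few percent lie well inside the variation between the arrays.

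Gene lists, 34 in all, were fixed before the data were examined, and 42 of their 1885 distinct symbols had no match in the reference. A gene's value was its probe set with the highest mean signal, and genes under the floor in all arrays were left out. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size matched on mean log2 signal in 20 bins. A list was called when this percentile was at most 2.5 or at least 97.5, and lists with fewer than 5 genes received no percentile. With 33 lists in the main comparison, a few can be outside that range by chance, and more can be where the genes of a list vary together. Between the 2 controls, 5 of 32 lists lay above it and 5 below it. The percentile describes these arrays and is not a test across samples. No list gene of the peptidoglycan recognition protein family was on the array under its name.

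The named genes were chosen by a rule written before the data were examined: the 12 highest and 12 lowest genes above the floor in all arrays and at least 2-fold the same way from both controls, ranked by the smaller difference; the 5 largest bounds in each direction; 4 members with the largest mean ratio from each called list and from the Toll-like receptor, inflammatory, interferon, apoptosis, p53 and Wnt lists; and the 5 highest and 5 lowest between the controls. Clone and systematic names were skipped. Outside the lists this ranking takes probe sets 1 by 1. Other probe sets of a named gene can differ from the printed one, and the clearest cases are given beside the value.

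The counts and lists were tested on simulated data built from the real signals. For PGRP-SC siRNA against control siRNA, run on 15502 probe sets, 87.0% of 100 probe sets changed by a log2 ratio of 1.5 and 100% of 100 changed by 2 passed the 2-fold threshold against both controls. Among 14811 unchanged probe sets, which included those under the floor, 0.155% did. The changed probe sets were drawn only from those with a mean log2 signal in the controls more than 2 above that of the floor. The shares of 87.0% and 100% therefore do not describe weaker probe sets. All 20 lists shifted by a log2 ratio of 0.5 were called, and 6% of 100 unshifted lists were. Those lists were random genes with independent noise, so this share need not hold for lists whose genes vary together. Because comparisons share arrays, 3 unchanged arrays were simulated 100 times with noise set by signal from the difference between the controls. That difference also holds any real effect of injection, and as 1 difference between 2 pools it can lie above or below the true spread. For the position of the control siRNA array a second simulation kept the PGRP-SC siRNA signals as measured and drew both controls around their mean.

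The alternatives tried were scaling to the same median, quantile normalization, cyclic loess, the deposited values with no further scaling, no floor, floors at the 20th and 60th percentiles, a pseudocount equal to the 40th percentile in place of the floor, ratios of at least 1.5 and 3, 1 probe set per gene, and the mean over a gene's probe sets. Added after the data were seen were the p53 and segmentation lists without members shared with other lists, and counts without the skeletal muscle list. Intervals for list medians came from 10000 bootstrap draws over genes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.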

Results

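Gene expression was measured in whole zebrafish embryos at 24 hours post-fertilization in 3 groups with 1 array each. The groups were uninjected embryos, embryos injected with a control siRNA, and embryos injected with an siRNA against zebrafish PGRP-SC, a member of the peptidoglycan recognition protein family, which binds a component of the bacterial cell wall. Each group was a pool of 400 embryos, and both siRNAs were given at 300 ng/µl in 1 nL per embryo. Each array gave a signal for 15617 probe sets, of which 15502 measured zebrafish transcripts. The median signal was 166.4 in the uninjected array, 169.6 in the control siRNA array and 161.6 in the PGRP-SC siRNA array. The arrays are single samples, so nothing here measures the spread between embryo pools, no p-value was computed, and their number limits the precision of every value. The difference between the 2 control arrays served as the background: 95% of the probe sets above the signal floor in both differed by less than 1.71-fold. The targeted gene comes first in such a design, but no probe set was named for a peptidoglycan recognition protein gene, so the knockdown itself was not analysed here.

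The comparison of PGRP-SC siRNA with control siRNA asks what differed in embryos given the targeting siRNA once injection is shared. By list median, segmentation and tail bud genes were higher with PGRP-SC siRNA and skeletal muscle genes were lower. The homeobox repressors ved and vox, which act in ventral patterning, were 8.95-fold and 4.04-fold higher, and msgn1, a transcription factor of the unsegmented paraxial mesoderm, was 3.34-fold higher. The nebulin gene neb and the muscle calcium channel subunit gene cacng1a had log2 ratios of -1.90 and -1.99. Of 9853 probe sets with a ratio, 279 were at least 2-fold higher and 345 at least 2-fold lower, 6.33% together (342 and 289 under median scaling, where higher outnumber lower), against 192 of 9799 or 1.96% between the controls.

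Of the 56 skeletal muscle genes measured, 22 were at least 2-fold lower and 1 was at least 2-fold higher, and the list's median log2 ratio of -0.94 lay below all 10000 random lists matched on signal. Fast troponin T tnnt3a had signals of 7366 in the uninjected, 3745 in the control siRNA and 1442 in the PGRP-SC siRNA array, and the muscle ubiquitin ligase gene trim63a had 726.7, 590 and 203.7. The array's own control probe sets for the muscle actin acta1 had 3' signals of 30281, 28895 and 19535 in the same order. Those for GAPDH, whose gene was also in the muscle list, went the other way, at 3436.7, 4798.9 and 6151.5. For acta1 the ratio of 5' to 3' signal, which is not a measure of expression, was 0.369, 0.205 and 0.127, while that of GAPDH was 0.350, 0.347 and 0.498. Of the 28 segmentation and tail bud genes, 9 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.52, above all random lists. The caudal-type homeobox gene cdx4 had signals of 589.6, 1496 and 4810 in the 3 arrays, and msgn1 had 305.6, 1362 and 4546, although its other probe set, at 34.33, 114.8 and 68.02, lay near or under the floor and did not show this.

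Of 23 p53 target genes, 6 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.51, also above all random lists. The growth arrest genes gadd45bb and gadd45ba had log2 ratios of 1.54 and 1.0, the ribosomal protein paralogue rps27l 1.39 and the sestrin gene sesn3 1.02. Also at least 2-fold higher than both controls were mdm2 and phlda3. Membership was that of the list as fixed, and whether p53 acted on these genes was not tested. The apoptosis list, with 19 genes, had a median of 0.48 at percentile 99.99, although 1 of its genes reached a 2-fold difference. Its member apaf1, the scaffold of the apoptosome, had a log2 ratio of 1.31, but its other probe set had 137.9 with control siRNA and 138.3 with PGRP-SC siRNA, and aifm1, a mitochondrial flavoprotein, had -0.89. The list's median lay within the random range, at percentile 92.96, when the floor was set at the 60th percentile of signals.

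Several signalling lists also had medians above the random range. The 31 TGF-beta and BMP genes had a median of 0.33 at percentile 99.98, with smad7 at 0.97 and the ligand gene bmp2b at 0.97, whereas id4 was at -0.88. The 26 FGF and MAP kinase genes had a median of 0.24 at percentile 99.13, with the ligand gene fgf8a at 1.42 and its feedback inhibitors il17rd and spry4 at 1.14 and 1.03. The 32 hypoxia and glycolysis genes had a median of 0.21 at percentile 99.54, led by pck1, which encodes a gluconeogenic enzyme, at 2.4 and the prolyl hydroxylase gene egln3 at 1.39, while the glycolytic aldolase gene aldoab was at -1.27. The lists share members: fgf8a is also in the segmentation and tail bud list and aldoab in the skeletal muscle list. The FGF and hypoxia medians without shared members were not computed. The 26 macrophage and neutrophil genes had a median of 0.22 at percentile 98.3, with cebpb at 1.3 and cebpa at 1.19. Going the other way, ctsz was at -0.95 and lysozyme lyz at -0.59. The 10 maternal and germ cell genes had a median of 0.39 at percentile 99.1. The germ plasm gene dnd1 was at 1.4, pou5f3 at 0.72, ccnb1 at 0.28 and nanos1 at -0.11. Against uninjected embryos dnd1 was at 0.80. The macrophage call was lost with no floor, with the floor at the 60th percentile and with a pseudocount, the maternal call with the floor at the 60th percentile, and the hypoxia call with a pseudocount.

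Besides skeletal muscle, 6 lists lay below the random range. The 18 pronephros and ion transport genes had a median of -0.44 at percentile 0.09, and the sodium pump subunit genes atp1a1a.3, atp1a1a.2 and atp1b1b had log2 ratios of -2.15, -1.52 and -1.13. The 52 notochord, cartilage and matrix genes had a median of -0.31, below all random lists, but their members went both ways: hapln1a, which encodes a hyaluronan link protein, was at -1.62, with 4 further probe sets from -0.86 to -1.51 and 1 at 0.41, and the laminin gene lamb1a was at 1.1. The 28 primitive erythrocyte genes had a median of -0.25 at percentile 0.68, with the anion exchanger gene slc4a1a at -1.6 and alas2, of heme synthesis, at signals of 411.1 with control siRNA and 206 with PGRP-SC siRNA. The 80 genes of neurons and neural progenitors had a median of -0.23 at percentile 0.06, with the brain fatty acid binding protein gene fabp7a at -1.86 and the synaptic gene snap25a at -1.30. Of the 80, 21 had a ratio above 0, among them egr2b at 1.03. The 40 proteasome and 59 oxidative phosphorylation genes had medians of -0.20 and -0.15 at percentiles 0.76 and 0.205. By the probe set with the highest mean signal, 0 of them were at least 2-fold apart in either direction. A weaker probe set of the proteasome gene psmd12 was at least 2-fold lower. Under quantile normalization the proteasome median was -0.17 at percentile 2.59, just inside the random range.

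The immune lists closest to the target's family lay within the random range, but 2 of these 3 depended on the floor. Most of their genes gave no value. Of 54 Toll-like receptor, 53 inflammatory and 46 interferon genes, 19, 24 and 20 were on the array under their names, and 15, 14 and 7 gave a ratio. The 15 genes of Toll-like receptor and NF-kB signalling had a median of 0.17 at percentile 87.1, with irak1bp1 at 1.15 and nfkb2 at 0.77. The 14 inflammatory and acute-phase genes had a median of 0.17 at percentile 89.6, and their members went both ways, ptgs1 at 1.0 and the complement gene c3a.1 at -0.84. The inflammatory median was 0.41 at percentile 99.28, outside the range, with the floor at the 60th percentile. It turned to -0.0855 with no floor and -0.055 with a pseudocount. The 7 interferon response genes had a median of 0.33 at percentile 95.2. With a pseudocount 20 genes gave 0.22 at percentile 99.74, outside the range. Also within the range were Wnt signalling at 0.14 with 35 genes, Notch signalling at 0.10 with 27, Hedgehog signalling at -0.15 with 14, heat shock and stress genes at 0.14 with 37, and cell cycle and DNA replication genes at 0.06 with 53. The remaining cell type lists within the range were endothelium at -0.14, heart muscle at 0.07, neural crest and pigment cells at 0.11, Hox cluster genes at -0.22, hatching gland at 0.12, yolk syncytial layer and liver at 0.07, circadian clock genes at 0.18, lens and retina at -0.01, and epidermis and periderm at 0.07. The endothelium median lay below the range at -0.56 with no floor and with the floor at the 20th percentile, and at -0.25 with a pseudocount. The heart muscle median turned to -0.16, -0.16 and -0.12 under these settings. The 68 cytosolic ribosomal protein genes had a median of 0.14 at percentile 96.4. The same median lay above the range with no floor, the floor at the 20th percentile, a pseudocount and the mean over probe sets. The sign of the lens median turned under median scaling, cyclic loess and the floor at the 60th percentile, which left 2 genes and no percentile, and those of the epidermis and ribosomal protein medians under quantile normalization.

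**Figure D1:**
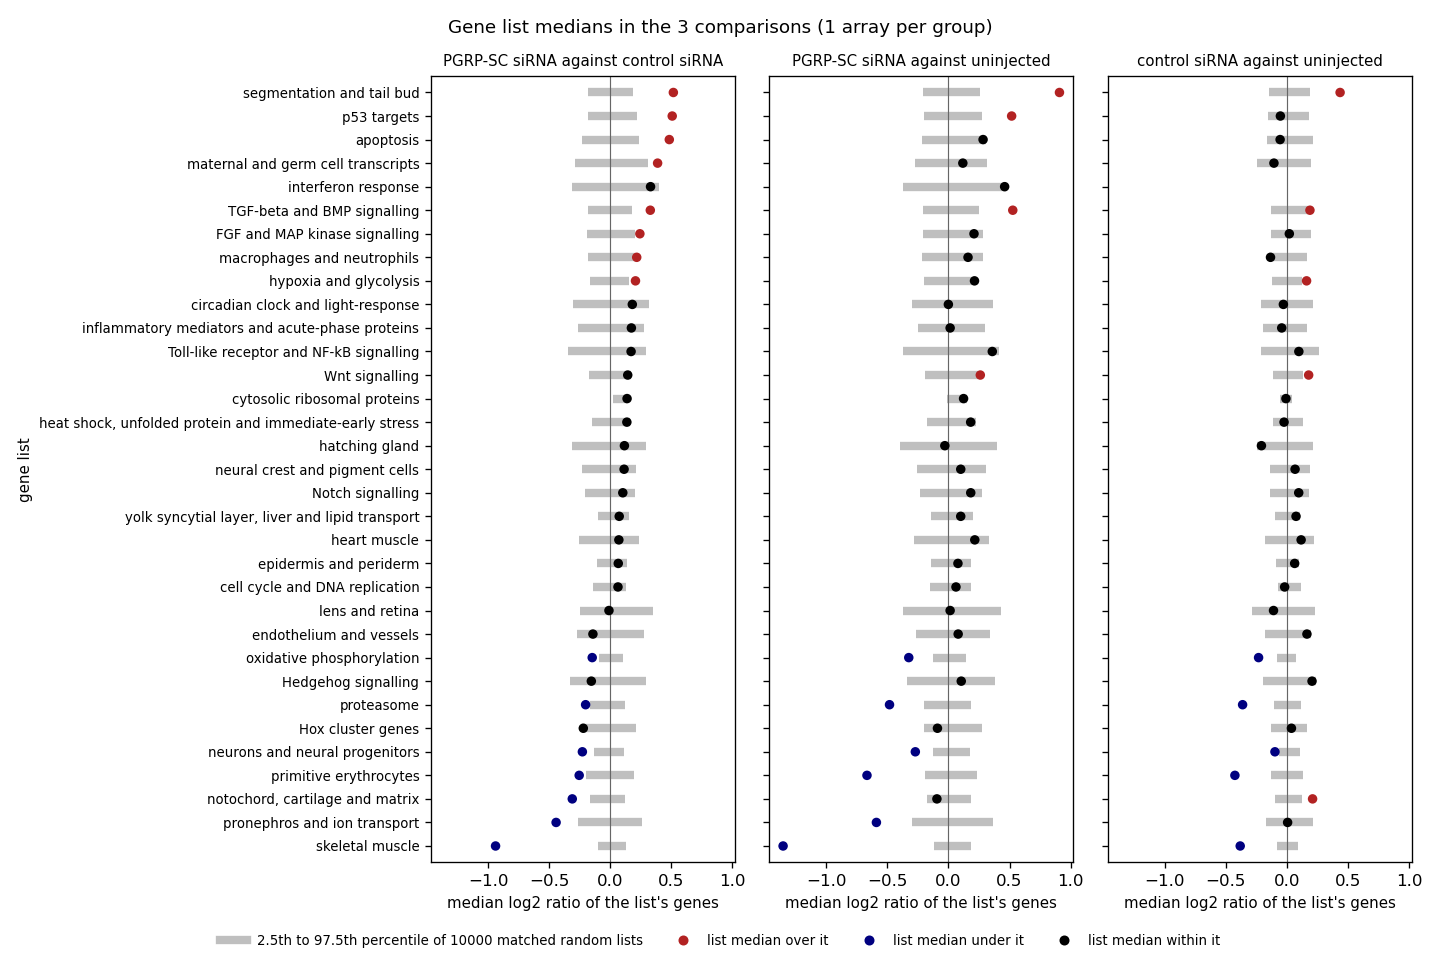
Median log2 ratio of each gene list (points) in the 3 comparisons, with the central 95% of 10000 random lists of equal size and matched signal (grey bars); each panel is 1 array against another. In PGRP-SC siRNA against control siRNA, 8 list medians lie over the range, led by segmentation and tail bud at 0.52, and 7 lie under it, with skeletal muscle farthest at -0.94. Between the controls 5 lie over it and 5 under it.

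The genes with the largest differences from both controls were of mixed function, and some belong to the lists. The carboxylesterase gene ces3 was 6.92-fold higher than with control siRNA and 5.46-fold higher than in uninjected embryos. The steroid synthesis gene cyp11a1.1 was 4.13-fold and 9.42-fold higher, and its signal also differed between the controls, at 536.3 with control siRNA and 235.2 without injection. Further genes among the 12 highest were ppp1r3cb, a glycogen-targeting phosphatase subunit, ctsll, irx7, tcima, slc3a2b and ampd2b, with log2 ratios against control siRNA of 1.85, 1.84, 1.78, 1.99, 1.73 and 1.73. Sizzled, szl, a secreted inhibitor in the BMP pathway, was under the floor in both controls and had a signal of 615.4 with PGRP-SC siRNA, a bound of at least 6.05-fold. The other 4 of the 5 largest bounds among named genes under the floor in both controls were tm4sf4, gcshb, foxi1 and cyp24a1, with signals of 676.6, 405.9, 355.5 and 352.7. Lowest was the D-amino acid oxidase gene dao.1, with signals of 3001 in the uninjected, 1645 in the control siRNA and 199.2 in the PGRP-SC siRNA array. It was followed by the thymosin gene tmsb and the keratin gene krt1-19e, whose signals were 2299 and 742.6 with control siRNA and 575.2 and 185.9 with PGRP-SC siRNA, with a second krt1-19e probe set going from 113.2 to 60.39, under the floor, and by ipo4, sulf2a, arvcfb, gpm6aa and tmx2a at log2 ratios of -1.81, -1.82, -1.78, -1.77 and -1.76. Among named genes under the floor in the PGRP-SC siRNA array alone, the 5 with the largest bounds were krt1-19d, lims2, sncgb, trim55b and ldb3a, whose signals with control siRNA were 351.1, 297.2, 280.6, 274.2 and 269.5. Another sncgb probe set went from 61.72 with control siRNA to 104.8 with PGRP-SC siRNA.

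Against uninjected embryos, the second control of the design, the skeletal muscle and segmentation medians were farther from 0. Skeletal muscle genes had a median log2 ratio of -1.35, with 38 of 56 at least 2-fold lower, and segmentation and tail bud genes a median of 0.91, with 12 of 28 at least 2-fold higher. The genes cdx4 and msgn1 were 8.16-fold and 14.9-fold higher, and neb and fabp7a had log2 ratios of -2.79 and -3.16. Of 9992 probe sets with a ratio, 556 were at least 2-fold higher and 633 at least 2-fold lower, 11.9% together.

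The p53 targets had a median of 0.52 at percentile 99.99, with 9 of 24 at least 2-fold higher, and the TGF-beta and BMP genes 0.53, above all random lists, with fsta, which encodes follistatin, at 1.35 and smad7 at 1.16. Wnt signalling, with 37 genes, had a median of 0.26 at percentile 98.3, with sp5l at 1.6, fzd7b at 1.02, dkk1b at 0.78 and dvl3a at 0.65, and its call was lost with no floor and with the floor at the 60th percentile. Primitive erythrocyte genes had a median of -0.67, proteasome genes -0.48 and oxidative phosphorylation genes -0.33, each below all random lists. Examples were slc4a1a at -2.6, alas2 at -2.19, the proteasome subunit gene psmd4a at -1.16 and the ATP synthase subunit gene atp5mc1 at -1.59. Pronephros genes had a median of -0.59 at percentile 0.04 and neuronal genes -0.27 at percentile 0.01. The apoptosis, FGF, macrophage, maternal, hypoxia and notochord medians, at 0.28, 0.21, 0.16, 0.12, 0.21 and -0.09, were within the random range in this comparison. Hypoxia lay above it in 4 of 9 alternatives, at 0.32 with quantile normalization, 0.29 with cyclic loess and with the floor at the 60th percentile, and 0.18 with a pseudocount. FGF did at 0.25 and 0.35 with the floor at the 20th and 60th percentiles, and apoptosis at 0.29 with the mean over probe sets. The macrophage median turned to between -0.0457 and -0.026 with no floor, the floor at the 20th percentile and a pseudocount, and the notochord median to 0.000784 with the floor at the 60th. Toll-like receptor signalling at 0.36, inflammatory genes at 0.01 and interferon response genes at 0.46 were also within the range. Interferon response genes lay above it in 5 of 9 alternatives, at 0.50, 0.50, 0.48, 0.16 and 0.46 with median scaling, quantile normalization, no floor, a pseudocount and the mean over probe sets, and had no percentile with the floor at the 60th, which left 2 genes. Inflammatory genes were at 0.65, above it, with the floor at the 60th percentile, and turned to -0.15, -0.17 and -0.0791 with no floor, the floor at the 20th percentile and a pseudocount.

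**Figure D2:**
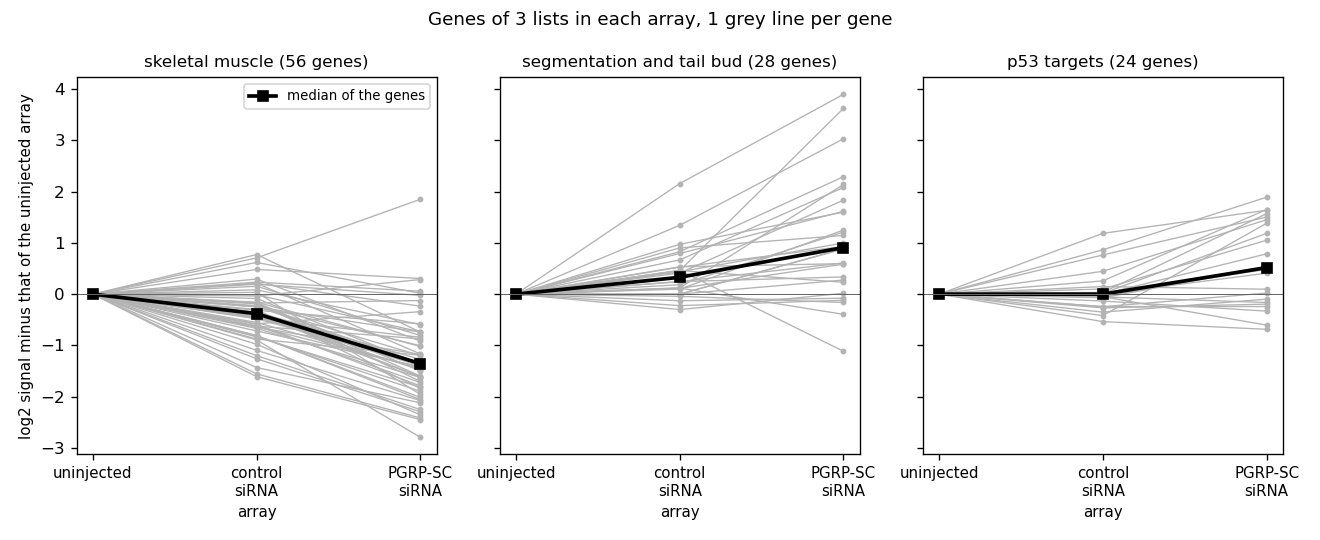
Log2 signal of each gene minus its value in the uninjected array (grey lines) and the median of the genes (black squares) for 3 lists across the 3 arrays, with signals under the floor set to the floor. The skeletal muscle median goes from -0.38 with control siRNA to -1.35 with PGRP-SC siRNA and the segmentation and tail bud median from 0.33 to 0.91, while the p53 target median reaches 0.52.

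The control siRNA and uninjected arrays differ by injection with an siRNA not directed at the target, and by all variation between 2 embryo pools and arrays. Between them, msgn1 was 4.46-fold higher with control siRNA and the urate oxidase gene uox 5.03-fold higher. The cartilage gene cnmd was 4.19-fold higher by a probe set whose signal with PGRP-SC siRNA was 92.99, under the floor. The stronger cnmd probe set had 319.5 in the uninjected and 568.7 in the control siRNA array, a log2 ratio of 0.83. The mitochondrial ADP/ATP carrier gene slc25a4 had a log2 ratio of -2.29, the lens crystallin gene crybb1 -1.79 and the secretory cell gene agr2 -1.71. Of 9799 probe sets with a ratio, 108 were at least 2-fold higher and 84 at least 2-fold lower.

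In this comparison the segmentation list had a median of 0.44 over 25 genes, above all random lists. It was 0.33 over 28 genes when those under the floor in both controls were kept. The notochord, Wnt, TGF-beta and hypoxia medians of 0.21, 0.18, 0.19 and 0.16 were above the range. Skeletal muscle at -0.38, primitive erythrocytes at -0.42, proteasome at -0.36 and oxidative phosphorylation at -0.23 were below all random lists, and neurons were at -0.10 at percentile 0.45. The p53 and apoptosis medians were both -0.05, at percentiles 21.6 and 20.235. The p53 median was 0.0166 without members shared with other lists. Further genes with large ratios were ppm1h and eif4a1a, at 1.96 and 1.64, although the stronger eif4a1a probe set had 6680 and 7068, a log2 ratio of 0.08, and a second krt1-19e probe set and fbxo44.5, at -1.96 and -1.65, of which the fbxo44.5 probe set may cross-hybridise. The notochord and TGF-beta calls were lost with a pseudocount, and the neuron call with the floor at the 60th percentile.

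Set against both other arrays at once, the PGRP-SC siRNA array had 219 probe sets at least 2-fold higher and 255 at least 2-fold lower (256 and 220 under median scaling, where higher outnumber lower). The higher set included 9 segmentation and tail bud genes, 6 p53 targets and 5 heat shock and stress genes, and the lower set included 20 skeletal muscle genes, 9 neuronal genes, 5 primitive erythrocyte genes and 5 pronephros genes. The same count was 126 for the uninjected array and 19 for the control siRNA array. Without the skeletal muscle list, an alternative added after the data were seen, the PGRP-SC siRNA counts were 218 and 233. Because comparisons share an array, 3 unchanged arrays were simulated 100 times with noise taken from the difference between the controls, which gave a mean of 28.2 probe sets apart for the PGRP-SC siRNA array and at most 41. For the uninjected array the draws reached at most 43, so its 126 also lay above all of them. For the control siRNA array they ran from 14 to 43, which holds its 19. The 2 PGRP-SC siRNA comparisons would share 16.0 higher and 22.2 lower probe sets if the lists were independent among 9675 probe sets. Independence leaves out the shared PGRP-SC siRNA array and the simulation leaves out any effect, so part of the excess over independence may come from that array, and 1 array cannot be divided to remove it. Across probe sets, which are not independent replicates, the log2 ratios of these comparisons had a covariance of 0.280, against a simulated mean of 0.0812, and a correlation of 0.82 against 0.50.

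For genes with several probe sets, 68 of 81 pairs with a member at least 2-fold apart had the same sign in PGRP-SC siRNA against control siRNA. Against uninjected embryos 131 of 144 did, and between the controls 35 of 39. The pairs came from 56, 109 and 29 genes. Some paired probe sets, as 2 of hapln1a, share a target sequence by their names, so the pairs are not all separate measurements. Both members were at least 2-fold apart in the same direction in 20, 31 and 1 of these pairs.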

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

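Among the array maker's control probe sets, 46 were taken as reporter and vector controls, which no comparison above uses. They are the controls with this array's species prefix, other than those for acta1 and GAPDH. Of the 46, 3 were above the signal floor in an array. Of those, 2 were over 10-fold apart between arrays. The first had a signal of 15050 in the uninjected, 125 in the control siRNA and 26710 in the PGRP-SC siRNA array, and the second had 412.6, 7.10 and 777.4 in the same order. In both the PGRP-SC siRNA array was the highest and the control siRNA array the lowest. What these probe sets detect is not given in the sources used here. By these 2 signals the 3 samples were not alike, at 213.8-fold and 109.5-fold between the highest and lowest array. The design text, however, has all embryos mixed before they were divided. The third control above the floor had signals of 25206, 25417 and 30279. What it detects is not given either, so its steadier signal does not show whether the samples were alike. Whether the difference in the first 2 signals arose in the embryo pools or in later handling was not tested. It also lies between the 2 arrays of the main comparison.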

How the results depend on the processing

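The tests without shared members and without the muscle list were chosen after the data were seen. With 1 array per group no array could be left out. Counts of probe sets depended on the floor and the threshold, by their construction, and under the 4 other scalings every count stayed within 1.5 times its main value. Under median scaling the balance turned: 342 higher and 289 lower against control siRNA, where the main counts were 279 and 345, and 607 and 577 against uninjected, where they were 556 and 633. It also turned for PGRP-SC siRNA apart from both others, at 256 and 220, where the main counts were 219 and 255. In each of the other settings the PGRP-SC siRNA counts against control siRNA were above those between the controls. The counts that follow are, as higher and lower, for PGRP-SC siRNA against control siRNA, against uninjected, for control siRNA against uninjected, and apart from both others for PGRP-SC siRNA, control siRNA and uninjected. With no floor they were 1450 and 1590, 1738 and 2107, 1082 and 1221, 731 and 1099, 356 and 607, and 537 and 640. With the floor at the 20th percentile they were 509 and 606, 828 and 1070, 240 and 254, 330 and 435, 37 and 40, and 141 and 135. With the floor at the 60th percentile they were 155 and 137, 317 and 317, 40 and 38, 128 and 108, 2 and 1, and 33 and 21. With a pseudocount they were 150 and 151, 328 and 373, 43 and 33, 122 and 114, 5 and 1, and 26 and 26. At a ratio of at least 1.5 they were 1060 and 1235, 1573 and 1589, 640 and 535, 823 and 895, 119 and 62, and 382 and 393. At a ratio of at least 3 they were 57 and 49, 149 and 180, 14 and 13, 50 and 32, 3 and 1, and 10 and 10. With 1 probe set per named gene they were 187 and 190, 375 and 400, 71 and 50, 154 and 152, 5 and 2, and 42 and 42.

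For the list medians 797 of the alternatives kept the direction and, where a percentile could be given, the side of the random range, none of the called lists changed sign, and the cause of the changes was not tested. The settings in brackets are the scaling, the percentile of the floor, no floor, the pseudocount, the mean over a gene's probe sets, or no shared members. Lists with fewer than 5 genes have no percentile and so no side: interferon response between the controls in the main setting and in those that leave it 4 or fewer genes, interferon response and lens and retina with the floor at the 60th percentile in every comparison, and maternal transcripts with that floor between the controls. Medians that came to lie within the range in PGRP-SC siRNA against control siRNA were apoptosis 0.19 (60th), proteasome -0.17 (quantile), macrophages 0.13 and 0.10 and 0.0747 (no floor, 60th, pseudocount), maternal transcripts 0.28 (60th), hypoxia 0.0857 (pseudocount). Medians that came to lie within the range in PGRP-SC siRNA against uninjected were Wnt signalling 0.23 and 0.24 (no floor, 60th). Medians that came to lie within the range in control siRNA against uninjected were TGF-beta 0.10 (pseudocount), neurons -0.0619 (60th), notochord 0.0948 (pseudocount). Medians that came to lie outside it in PGRP-SC siRNA against control siRNA were inflammatory genes 0.41 (60th), interferon response 0.22 (pseudocount), ribosomal proteins 0.14 and 0.14 and 0.14 and 0.14 (no floor, 20th, pseudocount, probe set mean), endothelium -0.56 and -0.56 and -0.25 (no floor, 20th, pseudocount). Medians that came to lie outside it in PGRP-SC siRNA against uninjected were inflammatory genes 0.65 (60th), interferon response 0.50 and 0.50 and 0.48 and 0.16 and 0.46 (median, quantile, no floor, pseudocount, probe set mean), apoptosis 0.29 (probe set mean), FGF 0.25 and 0.35 (20th, 60th), hypoxia 0.32 and 0.29 and 0.29 and 0.18 (quantile, loess, 60th, pseudocount). Medians that came to lie outside it in control siRNA against uninjected were Hedgehog signalling 0.19 and 0.27 and 0.16 and 0.24 (loess, 20th, pseudocount, probe set mean), endothelium 0.17 (probe set mean), maternal transcripts -0.32 (20th). Medians within the range, or with no percentile, that changed sign in PGRP-SC siRNA against control siRNA were inflammatory genes -0.0855 and -0.055 (no floor, pseudocount), ribosomal proteins -0.0079 (quantile), heart muscle -0.16 and -0.16 and -0.12 (no floor, 20th, pseudocount), lens and retina 0.13 and 0.10 and 0.00472 (median, loess, 60th), epidermis -0.0152 (quantile). Medians within the range, or with no percentile, that changed sign in PGRP-SC siRNA against uninjected were inflammatory genes -0.15 and -0.17 and -0.0791 (no floor, 20th, pseudocount), macrophages -0.0457 and -0.0299 and -0.026 (no floor, 20th, pseudocount), endothelium -0.0703 and -0.0703 and -0.0233 (no floor, 20th, pseudocount), heart muscle -0.0738 and -0.0839 and -0.0196 (no floor, 20th, pseudocount), lens and retina -0.51 and -0.43 and -0.28 and -0.17 and -0.0283 (no floor, 20th, 60th, pseudocount, probe set mean), notochord 0.000784 (60th), hatching gland 0.0118 and 0.00994 and 0.29 and 0.29 and 0.12 (median, quantile, no floor, 20th, pseudocount), circadian clock 0.0408 and 0.049 and 0.0444 and 0.16 and 0.0514 and 0.22 and 0.0763 (median, quantile, loess, no floor, 20th, 60th, pseudocount). Medians within the range, or with no percentile, that changed sign in control siRNA against uninjected were inflammatory genes 0.22 (60th), interferon response 0.0934 and 0.0934 and 0.0293 (no floor, 20th, pseudocount), p53 targets 0.0166 (no shared members), FGF -0.00511 and -0.0259 and -0.00922 (median, quantile, loess), ribosomal proteins 0.0077 and 0.0351 (quantile, loess), lens and retina 0.0108 and 0.00951 (no floor, pseudocount), neural crest -0.0189 (20th), pronephros -0.0453 and 0 and -0.0284 and -0.0194 and -0.0932 and -0.0228 (median, quantile, loess, no floor, 60th, probe set mean), maternal transcripts 0.00566 (60th).

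Of the ratios of named genes, 1881 kept their direction and their side of 2-fold, 35 came under 2-fold, 10 went past it and 6 ratios under 2-fold changed sign. Signal over background limits the low genes: 5332 probe sets were under the floor in all 3 arrays and give no ratio.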

Other observations

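The tests of scaling, RNA degradation and the 3 p53 explanations below, and the simulated shares of the third pattern, were chosen after the result they concern was seen. The early embryo list and the covariance were set before.

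A list of other genes active in the early embryo, which shares no symbol with the lists above, was higher in the PGRP-SC siRNA array. Its 42 measured genes had a median log2 ratio of 0.43 against uninjected and 0.20 against control siRNA, with 9 and 5 of them at least 2-fold higher and 0 lower. A list of late larval genes, with 25 and 24 measured, had medians of -0.26 and -0.28, at percentiles 0.845 and 0.31. Between the controls the early list's median was 0.23 at percentile 99.93, above its median for PGRP-SC siRNA against control siRNA, and the late list's was 0.02 at percentile 50.98.

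The first pattern weighed is that skeletal muscle genes were lower and segmentation genes higher in the PGRP-SC siRNA array. It held under the 5 scalings tried: the muscle median against control siRNA came no closer to 0 than -0.87 and the segmentation median stayed at or above 0.51. These scalings differed little, with median log2 ratios over the probe sets above the floor between -0.00384 and 0.0626. They could therefore hardly have removed the pattern. An earlier stage of the embryos of that array may account for it, since the separate early embryo list lay at percentile 100 of matched random lists against uninjected embryos, but that list was also at percentile 99.93 in the control siRNA array, so a shift in stage would not be of the PGRP-SC siRNA array alone. Whether an earlier stage reflects slower development after injection, after loss of the target, after this siRNA as such, or chance between pools cannot be decided with 1 array per group. RNA degradation cannot be told apart either, because the 5' to 3' ratio was lowest in this array for acta1 at 0.127 and highest for GAPDH at 0.498.

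The second pattern is that p53 target genes were higher in the PGRP-SC siRNA array. Between the controls, which differ by injection and by all variation between 2 pools, the list's median was -0.0523. Against control siRNA, which shares the injection, it was 0.51. The difference between the list's shifts in the 2 injected arrays was 0.59 over 20 genes, with an interval from -0.04 to 1.37. That interval leaves out genes under the floor in both controls and measures the spread among genes, not between pools. Injection of siRNA as such is therefore not excluded, and 1 array per group cannot decide it. The earlier stage that the segmentation genes show stays open as well: the p53 list's shift with control siRNA was -9.78% of its shift with PGRP-SC siRNA against 43.7% for segmentation over 25 genes, but the p53 interval of -301.4% to 351.3% contains both. A toxic effect of this siRNA that does not go through its target could equally raise these genes, and the series holds 1 siRNA against the target, so it cannot be told apart from an effect of the target. Without members shared with other lists, the p53 median was 0.601 against control siRNA.

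The third pattern is that the control siRNA array lies between the other 2 along the change from uninjected to PGRP-SC siRNA: among the 556 probe sets at least 2-fold higher with PGRP-SC siRNA than in uninjected embryos, control siRNA lay between in 503, or 90.5%, and among the 633 lower in 564, or 89.1%, at a median of 35.3% and 33.5% of the shift. In 100 simulations of 3 unchanged arrays 83.5 higher and 84.4 lower probe sets passed on average, with control siRNA between in 72.5% to 92.9% and 72.2% to 91.9%, at 31.6% to 59.6% and 44.5% to 70.26% of the shift. In 100 where only the PGRP-SC siRNA array differed 488.9 and 613.4 passed, with control siRNA between in at most 73.9% and 74.8%, at 7.35% to 16.9% and 11.9% to 20.06% of the shift, so the observed shares and shifts lie above every such draw. Noise of the array shared by both ratios would give a negative covariance between control siRNA against uninjected and PGRP-SC siRNA against control siRNA, simulated at -0.0870 to -0.0761, whereas 0.0128 was observed. A candidate explanation is a response to injection that both siRNAs share and that is larger with PGRP-SC siRNA, but with 1 array per group a difference between embryo pools stays open, and the first reporter control signal, 125 with control siRNA against 15050 and 26710, is not in this order.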
